A study of Arabidopsis thaliana with 12 samples.

How the data were processed

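Total RNA of Arabidopsis thaliana leaves was sequenced from the wild type Col and the mutant line chlorella-1 at 14 d and 26 d. Per the labels, each of the 4 groups holds 3 libraries, 12 in all, made with a stranded total RNA kit that removes plant ribosomal RNA. The labels give no batch or date, and do not say whether libraries with the same replicate number share plants, trays or days.

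The deposited table lists 38338 features with a read count and an FPKM value per library. The read counts were used as deposited: per the file headers they are whole-number counts per gene, and they were checked to be whole numbers whose totals differ between libraries, as raw counts do. Per the submitters' processing notes, STAR, HISAT2, HTSeq, StringTie and DESeq2 were used with the genome build TAIR10, but versions, the role of each tool and the strand setting of the counting are not stated. The authors' 12 deposited FPKM columns were left out, because the counts hold the same libraries and 3 FPKM columns carry no replicate number. Another 50 rows, all mitochondrial, name no gene and were left out of the gene tests; they held 0.0771% to 0.216% of the counts of a library. All 38288 remaining gene IDs were found in the reference annotation of TAIR10.1, which supplied loci, coordinates, gene types and overlaps, and 9983 of them had 0 counts in every library. Group and replicate were taken from the column names.

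Libraries held 45120547 to 70452171 counts. Nuclear genes took 26.9% to 49.4% of the counts of a library and plastid genes most of the rest, while ribosomal and transfer RNA genes held 0.0376% to 0.137%.

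Gene counts were tested with edgeR 4.0.16 in R 4.3.3. The filterByExpr function kept 20398 genes, libraries were scaled by the trimmed mean of M values (TMM), and 1 quasi-likelihood model with a term for each group was fitted to all 12 libraries, so that the groups share an estimate of the spread. From it came 5 comparisons: chlorella-1 against Col at each age, 26 d against 14 d in each genotype, and the difference between the genotypes in the age change. Tests were two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05 on the adjusted p. CPM are read counts normalised to the TMM-scaled library size, as edgeR computes them. For a gene with 0 counts over a whole group, a fold is given as a lower bound against a floor of 3 counts over that group. With 1 to 3 counts, it is a ratio with a 95% exact (Clopper-Pearson) counting interval. Intervals and floors cover counting error only.

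The design, the rule for naming genes, 25 gene lists and most alternative settings were fixed before the data were examined. Of the lists, 22 had at least 3 measured members and were tested with camera (limma 3.58.1, voom values, preset inter-gene correlation 0.01) with Benjamini-Hochberg adjustment over the 110 tests of 22 lists in 5 comparisons. The tests were repeated with an estimated correlation and with fry. Marker lists of dividing cells, root, and epidermis with trichomes had fewer than 3 measured members and gave no test. The naming rule took, per comparison, the 6 genes with the largest and the 6 with the smallest log2 fold change among genes that passed, whose groups did not overlap, that reached 5 CPM in a compared group and that carry a symbol. It also took up to 4 members per list with the smallest p, and always GLK1, GLK2, ORE1, NAP, NYE1, SAG12, psbA, rbcL, LHCB1.4 and RBCS1A. For a CHLORELLA gene that neither the table nor the annotation names, noncoding genes lower in chlorella-1 at both ages were to be given as values. Where names differ, ORE1 is NAC6 in the table, NAC055 and ORS1 are both NAC3, LHCB1.4 is LHB1B1, GLK1 is GPRI1, LUX is PCL1, HB7 is HB-7 and RPOTp is SCA3; they were matched by locus.

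The share of counts from plastid-encoded genes, with ribosomal and transfer RNA genes left out, was compared by two-sided exact permutation tests, whose smallest p with 3 against 3 is 0.1. Log2 fold changes of different comparisons were related across genes, which are not independent replicates. Where comparisons share Col libraries, 20 simulations of unchanged groups gave the covariance that shared libraries produce alone. In these simulations, too, a gene had the same spread in every group. Their correlation holds for groups without any change and is no reference for the observed one.

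The alternatives chosen beforehand were DESeq2 size factors in edgeR, scaling on nuclear genes, removal of ribosomal and transfer RNA genes, no filter, a filter of 10 counts in every library of a group, limma voom, DESeq2 1.42.0, a minimum absolute log2 fold change of 1, a fit of only the groups compared, the replicate number as a block, and each library left out in turn. Added after seeing the data were fits without the chlorella-1 group at 26 d, with psbA left out of counts and library sizes, and of only the groups compared with a block or with each library left out. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

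The gene tests of the 4 comparisons between 2 groups were run on simulated counts drawn from the real means and library sizes, with 200 genes changed. Each gene was given the same spread in every group, whereas the real libraries of chlorella-1 at 26 d vary most. The shares recovered hold for equal spread only. In the simulation of chlorella-1 against Col at 14 d, over 20044 genes, the test recovered 32% of genes changed 2-fold and 88% of those changed 4-fold. At 26 d, over 19416 genes, it recovered 29% and 86%. For the age change in Col, over 20018 genes, it recovered 30% and 89%, and for that in chlorella-1, over 19266 genes, 40% and 91%.

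Counts are uncertain for genes that overlap another gene, on either strand, since the strand setting is not stated. They are also uncertain for near-identical copies, here the PDF1.2 family, the RBCS and LHCB1 genes, small nuclear RNA genes, and plastid genes of the inverted repeat.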

Results

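Leaves of the plant Arabidopsis thaliana were compared between the wild type Col and chlorella-1, a mutant line of a gene for a long noncoding RNA, at 14 d and at 26 d of age. RNA depleted of ribosomal RNA was sequenced from 3 libraries per group, 12 in all. Total read counts were 70452171, 68957032 and 56405611 in Col at 14 d, and 63429547, 65394628 and 58281402 in chlorella-1 at 14 d. At 26 d they were 58717744, 58034270 and 58833770 in Col, and 62688704, 55903119 and 45120547 in chlorella-1. Neither the gene table nor the annotation names a CHLORELLA gene, so the RNA that the mutation should reduce could not be checked, and the genotypes are as labelled. Across genes, replicates of a group correlated with Spearman's rho of 0.991 to 0.992 in Col at 14 d, 0.989 to 0.992 in chlorella-1 at 14 d, 0.969 to 0.982 in Col at 26 d and 0.929 to 0.971 in chlorella-1 at 26 d. Gene levels below are normalised read counts (CPM) as mean ± SD with n = 3, and log2 fold changes carry their standard error. Adjusted p values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists from camera.

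Transcripts of the plastid genome made up most of the counted RNA in every group, and the 26 d mutant leaves held the smallest share. In Col, 67.6% ± 1.72 of the counts came from plastid-encoded genes at 14 d and 71.9% ± 0.547 at 26 d (SD, n = 3). In chlorella-1 the share was 71.4% ± 1.16 at 14 d and 55.8% ± 5.82 at 26 d (SD, n = 3). At 14 d the mutant lay 3.79 percentage points above Col, and at 26 d its share was lower, with a difference of -16.1 percentage points. Much of this RNA was psbA, which encodes the D1 protein of photosystem II and took 40.3% ± 2.88 of the counts in Col at 14 d and 57.4% ± 1.12 at 26 d, against 48.0% ± 1.5 and 52.1% ± 6.27 in chlorella-1. With psbA left out, the plastid share was 45.7% ± 1.3 in Col at 14 d, 45% ± 0.687 in chlorella-1 at 14 d, 34.1% ± 1.31 in Col at 26 d and 7.88% ± 1.17 in chlorella-1 at 26 d. Its difference between the genotypes then turned to -0.729 percentage points at 14 d (two-sided exact permutation p = 0.5) and grew to -26.2 at 26 d. Without psbA the change with age was -11.7 percentage points in Col, where it had been 4.38, and -37.1 in chlorella-1, where it had been -15.5. All the other differences of shares named here had groups that did not overlap, which chance gives in 10% of cases, and an exact permutation p of 0.1, the smallest that 3 against 3 allow. The exceptions were psbA alone between the genotypes at 26 d (exact permutation p = 0.3) and with age in chlorella-1 (exact permutation p = 0.4).

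**Figure D1:**
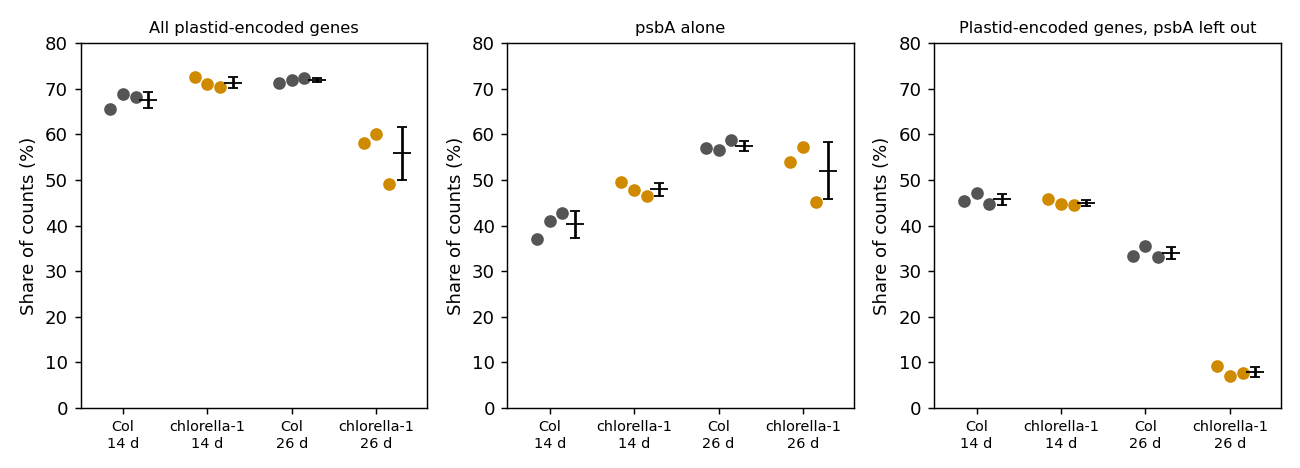
Share of read counts, in percent, from all plastid-encoded genes, from psbA alone and from plastid-encoded genes with psbA left out, with a point for each of the 12 libraries and bars for group means and SD (n = 3). The 26 d chlorella-1 group averages 55.8%, against 71.9% in Col of that age.

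The first comparison asked how chlorella-1 leaves differed from Col leaves at 14 d. Of 29 senescence genes, 3 passed singly, all of them genes of transcription factors at low levels. The NAC factor ORS1 (AT3G29035) rose from 0.850 ± 0.323 to 5.98 ± 1.31 CPM (log2 fold change 2.81 ± 0.29, adjusted p = 0.00295). ORE1 (AT5G39610) rose from 0.228 ± 0.122 to 1.39 ± 0.515 CPM (2.59 ± 0.41, adjusted p = 0.0347) and NAC055 (AT3G15500) from 0.0430 ± 0.0376 to 0.487 ± 0.2 CPM (3.51 ± 0.57, adjusted p = 0.0412). Genes of chlorophyll synthesis, the Calvin cycle and the plastid's own ribosomes lay somewhat lower as lists, which did not pass with an estimated correlation (adjusted p = 0.328, 0.375 and 0.375). The light-harvesting and photosystem lists did not pass. In all, 33 of 20398 genes passed, 24 higher and 9 lower in the mutant.

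Other genes named by rule at 14 d follow. The monosaccharide transporter STP1 (AT1G11260) rose from 34.6 ± 4.61 to 117 ± 38.2 CPM and the sucrose exporter SWEET12 (AT5G23660) from 2.24 ± 0.264 to 5.88 ± 0.436. The dormancy-associated gene DYL1 (AT1G28330) rose from 4.55 ± 0.272 to 20.3 ± 6.29 and the phloem protein gene PP2-A13 (AT3G61060) from 22.1 ± 1.70 to 61.3 ± 13.9. Their log2 fold changes were 1.76 ± 0.30, 1.39 ± 0.22, 2.16 ± 0.28 and 1.47 ± 0.23, with adjusted p of 0.0496, 0.0387, 0.0159 and 0.0347. Lower were SAPX (AT4G08390), the stromal ascorbate peroxidase, from 8.01 ± 1.31 to 3.05 ± 0.451 CPM (-1.39 ± 0.19, adjusted p = 0.0159), and CPN20 (AT5G20720), a chloroplast co-chaperonin, from 65.7 ± 9.94 to 28.2 ± 4.94 (-1.22 ± 0.18, adjusted p = 0.0209). STP1, PP2-A13 and CPN20 overlap genes on the other strand, and counts for such pairs are uncertain. The microRNA precursor MIR850 (AT4G13493, chromosome 4, 7845707 to 7845927) fell from 6.70 ± 0.0387 to 0.0291 ± 0.0374 CPM (-7.75 ± 0.51, adjusted p = 5.16e-05). It lies within a noncoding gene of the same strand, AT4G13495, which did not pass. The noncoding AT2G01422 had 1.88 ± 0.122 CPM in Col and 0 counts in the mutant (adjusted p = 0.000509), at least 108-fold lower against a floor of 3 counts over the group. Likewise, AT3G05955 fell from 1.10 ± 0.154 to 0.0345 ± 0.0357 CPM (-4.90 ± 0.69, adjusted p = 0.0195). SEN1, a gene induced by darkness and senescence, stood at 51.6 ± 33.8 against 6.73 ± 2.32 CPM (adjusted p = 0.0706, 2.11e-06 to 0.447 over the alternatives). MIR850, ORS1 and AT2G01422 passed under all 30 alternatives, and the other 9 called genes each lost the call without some library in the fit of all groups. Without Col replicates 1, 2 and 3 at 14 d, calls were lost for 9, 9 and 8 of them (adjusted p up to 0.348 for STP1, 0.218 for SWEET12 and 0.194 for STP1), and without chlorella-1 replicates 1, 2 and 3 for 9, 7 and 8 (up to 0.228 for STP1, 0.109 for AT3G05955 and 0.144 for STP1). Of 26 d libraries, Col replicate 1 ended 3 of the calls (0.0571 for NAC055), replicate 2 another 3 (0.0765 for STP1), replicate 3 ended 4 (0.0755 for STP1) and chlorella-1 replicate 1 ended 5 (0.0802 for STP1). With only the 14 d groups fitted, all 33 genes called at 14 d kept the call without any 1 library of those groups.

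Of the 22 gene lists, 9 passed at 14 d, all by small shifts. Chlorophyll biosynthesis genes lay lower (17 measured, median log2 fold change -0.53, adjusted p = 6.67e-08, and adjusted p = 0.328 with an estimated correlation). None of them passed over all genes, while 5 were lower when adjusted over the list alone and 11 with only the 14 d groups fitted. CHLI1, a magnesium chelatase subunit, stood at -1.05 ± 0.25 (adjusted p = 0.162) and GSA1, which makes the precursor aminolevulinate, at -0.81 ± 0.16 (adjusted p = 0.09). Calvin cycle genes also lay lower (17 measured, median -0.56, adjusted p = 3.27e-05, and adjusted p = 0.375 with an estimated correlation). No member passed over all genes or adjusted over the list alone, while 12 of 17 were lower with only the 14 d groups fitted. RBCS1A, for the small Rubisco subunit, stood at -0.75 ± 0.25 (adjusted p = 0.312, 0.000613 to 0.923 over the alternatives). The plastid-encoded ribosomal protein genes (21 measured, median -0.31, adjusted p = 3.43e-06) and the nuclear plastid transcription machinery (20 measured, median -0.32, adjusted p = 0.000129) were lower too, each with adjusted p = 0.375 with an estimated correlation and with 0 members called either way. Examples are rpl22 at -0.58 ± 0.19 (adjusted p = 0.314) and the polymerase gene RPOTp at -0.71 ± 0.24 (adjusted p = 0.337). In the fit of only the 14 d groups, 11 of 21 ribosomal genes were lower, and 6 of 20 transcription genes were lower and 1 higher. That fit had 4 oxidative stress genes lower and 1 higher. Oxidative stress genes had a median of 0.02, a mean of -0.42 and a test for lower values (13 measured, adjusted p = 0.0353, and adjusted p = 0.375 with an estimated correlation), with 0 called and 3 lower adjusted over the list alone, such as the superoxide dismutase CSD2 (-1.30 ± 0.24, adjusted p = 0.0666).

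Leaf senescence genes lay higher as a list at 14 d (29 measured, median 0.52, adjusted p = 8.03e-07, and adjusted p = 0.328 with an estimated correlation). ORS1, ORE1 and NAC055 were the 3 members that rose, while 9 were higher when adjusted over the list alone and 10 with only the 14 d groups fitted. The median was 0.50 without the 3 members near 0 counts, among them SAG12, which had 0 counts in both groups. NAP stood at 0.91 ± 0.25 (adjusted p = 0.228) and the Mg-dechelatase gene NYE1 at 0.28 ± 0.19 (adjusted p = 0.769). Jasmonate genes (13 measured, median 0.64, adjusted p = 0.00309, and adjusted p = 0.328 with an estimated correlation) were also higher, with 0 called and 2 higher adjusted over the list alone. Abscisic acid, cold and drought genes (11 measured, median 0.53, adjusted p = 0.00564, and adjusted p = 0.41 with an estimated correlation) lay higher with 0 called either way. Clock genes (11 measured, median 0.24, adjusted p = 0.00727, and adjusted p = 0.332 with an estimated correlation) had 0 called and 1 higher adjusted over the list alone. Examples are OPR3 at 0.79 ± 0.23 (adjusted p = 0.235), NCED3 at 1.07 ± 0.42 (adjusted p = 0.439) and PRR5 at 0.97 ± 0.24 (adjusted p = 0.169). With only the 14 d groups fitted, 3 jasmonate, 4 abscisic acid and 4 clock genes were higher. The jasmonate list lost its call without Col replicate 1 at 14 d (adjusted p = 0.0589). The oxidative stress list lost its own without Col replicates 1 (0.0677) and 3 (0.0545) at 14 d, chlorella-1 replicate 2 at 14 d (0.0863) and chlorella-1 replicate 2 at 26 d (0.0915).

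The remaining 13 lists did not pass at 14 d. Plastid-encoded photosystem, cytochrome and Rubisco genes had a median of 0.10 (27 measured, adjusted p = 0.0833), ATP synthase genes -0.15 (6 measured, adjusted p = 0.202) and RNA polymerase and other plastid genes -0.20 (8 measured, adjusted p = 0.146), with 0 members called. Plastid-encoded NDH genes had a median of 0.02, a mean of -0.01 and adjusted p = 0.981 (11 measured). Nuclear light-harvesting genes had a median of -0.03 (20 measured, adjusted p = 0.277, 1 member lower adjusted over the list alone), with LHCB1.4 at 0.22 ± 0.57 (adjusted p = 0.995) and LHCB4.3 at -1.46 ± 0.36 (adjusted p = 0.162). Nuclear photosystem and electron transport genes had a median of -0.17 (27 measured, adjusted p = 0.0623). Fitted on the 14 d groups alone, 4 light-harvesting, 7 nuclear photosystem and 3 RNA polymerase list genes were lower, and 2 plastid photosystem list genes were higher. The chloroplast regulators GLK1 and GLK2 stood at 0.15 ± 0.37 and 0.14 ± 0.44 (adjusted p = 0.994 and 1.0), and their list of 6 at a median of 0.09 (adjusted p = 0.88). For psbA the value was 0.38 ± 0.30 (adjusted p = 0.825, 0.00437 to 1.0 over the alternatives) and for rbcL -0.20 ± 0.25 (adjusted p = 0.934). Salicylic acid and defence genes (-0.28, adjusted p = 0.314), heat shock genes (-0.10, adjusted p = 0.544) and flavonoid genes (0.14, adjusted p = 0.924) did not pass. Neither did markers of floral organs (adjusted p = 0.329) and guard cells (-0.11, adjusted p = 0.893). Vascular markers had a median of 0.14, a mean of -0.07 and adjusted p = 0.747, with SWEET12 called.

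The count of 33 at 14 d depended on which libraries were fitted and on the test used. It stood beside 1851 genes at an unadjusted p under 0.05, 381 in DESeq2, and 2713 (1190 higher and 1523 lower) when the 6 libraries of 14 d were fitted alone, and both of those sets held all 33. In the fit of all groups, without single libraries of 14 d, it was 6, 5 and 9 (Col replicates 1, 2 and 3) and 6, 16 and 9 (chlorella-1 replicates 1, 2 and 3), and without chlorella-1 replicates 1 and 2 at 26 d it was 17 and 232.

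At 26 d, chlorella-1 leaves held far less RNA of photosynthesis genes than Col leaves and more of most senescence genes, among them NYE1 of chlorophyll breakdown. NYE1, whose product removes magnesium from chlorophyll, rose from 57.1 ± 10.5 to 1396 ± 295 CPM (log2 fold change 4.61 ± 0.22, adjusted p = 2.1e-07). The cysteine protease gene SAG12, a marker of late senescence, rose from 113 ± 72.6 to 3217 ± 1283 CPM (4.83 ± 0.57, adjusted p = 0.000199). CHLM, a methyltransferase of chlorophyll synthesis, fell from 35.1 ± 9.60 to 2.93 ± 0.298 CPM (-3.58 ± 0.22, adjusted p = 4.34e-07). Of 20398 genes, 6429 were higher and 6492 lower, 12921 in all, or 6998 and 5882 with DESeq2 size factors. With only the 26 d groups fitted, 5530 were higher and 4358 lower, and 4657 and 3096, 4612 and 2744, and 4396 and 2687 when Col replicates 1, 2 and 3 were also left out.

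Genes of the photosynthetic apparatus fell almost without exception at 26 d, in the nucleus and in the plastid. All 20 nuclear light-harvesting genes fell (median log2 fold change -3.21, adjusted p = 2.87e-09, and adjusted p = 0.328 with an estimated correlation), such as LHCB6 from 556 ± 220 to 47.6 ± 4.84 CPM (-3.55 ± 0.28) and LHCB1.4 from 373 ± 332 to 19.5 ± 9.51 (-4.26 ± 0.65). All 27 nuclear photosystem and electron transport genes fell (median -2.67, adjusted p = 2.58e-11, and adjusted p = 0.339 with an estimated correlation), among them PSAG at -3.03 ± 0.22. The 17 Calvin cycle genes all fell (median -2.82, adjusted p = 5.61e-08, and adjusted p = 0.332 with an estimated correlation), with RBCS1A going from 658 ± 244 to 86.3 ± 8.75 CPM (-2.93 ± 0.26). Of 17 chlorophyll biosynthesis genes 15 fell and 2 did not pass (median -2.11, adjusted p = 2.21e-06, and adjusted p = 0.332 with an estimated correlation). Adjusted over the list alone, 15 were lower and 1 higher there, and for the light-harvesting, photosystem and Calvin cycle lists the counts adjusted over the list alone were those over all genes.

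Most plastid-encoded genes fell with them at 26 d. Of 27 photosystem, cytochrome and Rubisco genes 24 fell (median -1.40, adjusted p = 1.55e-09, and adjusted p = 0.328 with an estimated correlation), for instance rbcL, the large Rubisco subunit, at -2.96 ± 0.27 (adjusted p = 4.08e-06) and psbE from 1447 ± 151 to 382 ± 21.9 CPM (-1.92 ± 0.16). In contrast, psbA stood at -0.04 ± 0.30 (adjusted p = 0.915, 0.221 to 1.0 over the alternatives). The genes psbM and psbN, singled out after their values were seen, did not pass either (-0.55 ± 0.28, adjusted p = 0.106, and -0.51 ± 0.33, adjusted p = 0.196). All 6 ATP synthase genes fell (median -2.48, adjusted p = 4.58e-05, and adjusted p = 0.332 with an estimated correlation), atpH from 1119 ± 192 to 170 ± 8.37 CPM (-2.72 ± 0.17). All 11 NDH genes fell (median -2.66, adjusted p = 2.15e-07, and adjusted p = 0.328 with an estimated correlation), ndhA from 897 ± 193 to 121 ± 11.7 (-2.89 ± 0.19). All 21 ribosomal protein genes of the plastid fell (median -1.64, adjusted p = 1.62e-08, and adjusted p = 0.332 with an estimated correlation), such as rps2 at -2.06 ± 0.20. Of the 8 RNA polymerase, accD, clpP and ycf genes 7 fell (median -1.36, adjusted p = 0.00862, and adjusted p = 0.415 with an estimated correlation), rpoC1 from 280 ± 23.6 to 58.4 ± 26.5 CPM (-2.26 ± 0.26). The nuclear machinery of plastid transcription fell in 18 of 20 genes (median -1.34, adjusted p = 3.27e-05, and adjusted p = 0.339 with an estimated correlation), such as the sigma factor gene SIG4 at -2.60 ± 0.24. Its 1 member that rose was RPOTmp, a phage-type polymerase of both organelles (1.29 ± 0.31, adjusted p = 0.00345), a call lost with only the 26 d groups fitted and Col replicate 3 left out (0.0585, 6.21e-05 to 0.0585 over the alternatives). In all of these lists the counts adjusted over the list alone were the same.

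**Figure D2:**
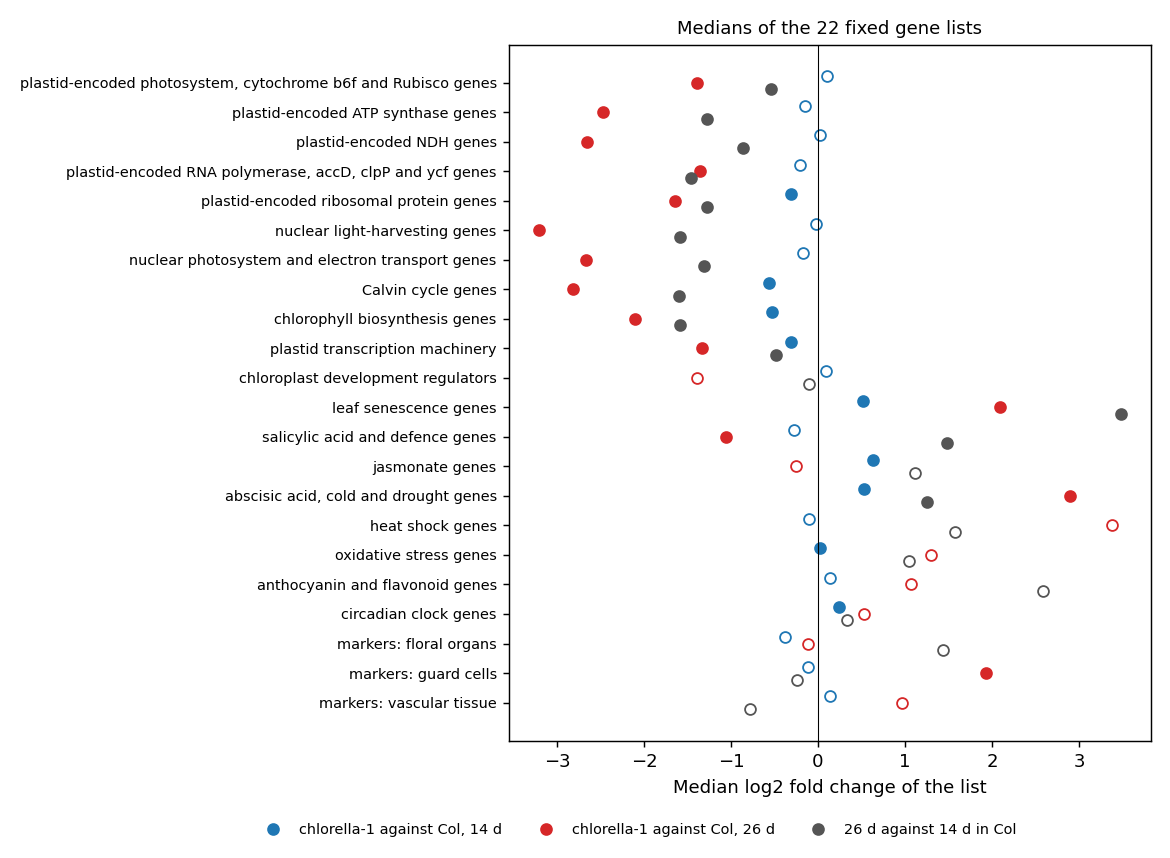
Median log2 fold change of each of the 22 gene lists in chlorella-1 against Col at 14 d and at 26 d and in 26 d against 14 d in Col, with filled points for lists that passed camera with the preset correlation. At 26 d the medians of the photosynthesis lists lie between -3.21 and -1.40, and that of senescence genes at 2.1.

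Chloroplast regulators went both ways at 26 d. GLK1 (-1.87 ± 0.39, adjusted p = 0.00135) and GLK2 (-1.70 ± 0.46, adjusted p = 0.00666), which drive photosynthesis genes, were among the 4 of 6 list members that fell, while HY5, a light-signalling factor, rose from 2.42 ± 0.493 to 23.2 ± 9.70 CPM (3.25 ± 0.32) as 1 of 2. The list as a whole did not pass (median -1.39, adjusted p = 0.544). The GLK calls were lost in some fits of the 26 d groups alone: GLK1 without Col replicate 3 (0.0535) or chlorella-1 replicate 1 (0.0511; 2.5e-06 to 0.0535 over the alternatives), and GLK2 without Col replicates 1 (0.0744), 2 (0.0888) or 3 (0.106) or chlorella-1 replicate 1 (0.0611; 2.14e-05 to 0.106).

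Leaf senescence genes rose in 21 of 29 cases and fell in 3 at 26 d (median 2.1, adjusted p = 4.21e-06, and adjusted p = 0.328 with an estimated correlation), with 22 higher and 3 lower adjusted over the list alone. The chlorophyll catabolism genes NYC1 and PPH rose from 288 ± 56.9 to 3174 ± 603 CPM (3.46 ± 0.22) and from 117 ± 20.7 to 729 ± 195 (2.63 ± 0.21). The senescence regulators ORE1, NAP and NAC055 rose by 3.24 ± 0.35, 1.88 ± 0.25 and 5.96 ± 0.41 on the log2 scale, NAC055 from 28.0 ± 5.08 to 1742 ± 316 CPM. Among the 3 lower members were SAG101, which acts in disease resistance as well (-1.49 ± 0.24, adjusted p = 0.000258), and SEN1 (-1.89 ± 0.52, adjusted p = 0.00799). SEN1 is given here after its values were seen, as is STP1, which fell from 96.1 to 34.8 CPM (-1.46 ± 0.29, adjusted p = 0.00115), opposite to its rise at 14 d.

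Hormone and stress lists split at 26 d. Salicylic acid and defence genes fell in 10 of 19 cases and rose in 1 (median -1.05, adjusted p = 0.0344, and adjusted p = 0.621 with an estimated correlation), WRKY70 at -2.0 ± 0.46 (adjusted p = 0.00266) and WRKY33 as the riser at 1.71 ± 0.27 (adjusted p = 0.000199). That list's call was lost without Col replicate 2 (0.108) and without chlorella-1 replicate 1 (0.157) at 26 d, and WRKY70 lost its own with only the 26 d groups fitted and Col replicate 2 left out (0.0616, 0.000214 to 0.0616 over the alternatives). Abscisic acid, cold and drought genes rose in 8 of 11 cases (median 2.89, adjusted p = 0.0105, and adjusted p = 0.432 with an estimated correlation), NCED3, which makes the hormone's precursor, from 16.6 to 208 ± 117 CPM (3.65 ± 0.46). Jasmonate genes rose in 4 of 13 cases and fell in 4 (median -0.26, adjusted p = 0.981), with the repressor gene JAZ1 at 4.70 ± 0.53. Among the fallers were plant defensin genes: PDF1.2 went from 39.7 ± 39.9 to 0.125 ± 0.0886 CPM (-8.39 ± 1.09, adjusted p = 5.48e-05), and its near-identical copies PDF1.2b and PDF1.3 from 7.02 ± 7.04 and 11 ± 11.3 CPM to 0 counts, at least 406-fold and 635-fold lower (adjusted p = 0.00185 and 0.000466). PDF1.2c stood at -7.85 ± 1.31 (adjusted p = 0.000322). Reads of these copies cannot be told apart with certainty. Heat shock genes rose in 5 of 6 cases (median 3.38, adjusted p = 0.092), HSP70 by 3.84 ± 0.50. Oxidative stress genes rose in 8 of 13 and fell in 3 (median 1.3, adjusted p = 0.124), with the alternative oxidase AOX1A at 2.96 ± 0.26 and the catalase CAT2 at -1.45 ± 0.23. Flavonoid genes rose in 2 of 10 cases (median 1.07, adjusted p = 0.251), among them TT5 at 1.15 ± 0.26. Clock genes rose in 5 of 11 and fell in 3 (median 0.53, adjusted p = 0.57), LUX at 1.98 ± 0.31 and RVE8 at -1.26 ± 0.18. Counts adjusted over the list alone were the same in these lists.

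Markers of other leaf cell types moved as well at 26 d. Guard cell markers rose in 3 of 4 cases (median 1.93, adjusted p = 0.0391, and adjusted p = 0.332 with an estimated correlation), the potassium channel gene KAT1 from 4.79 to 31.0 CPM (2.69 ± 0.20), a list call lost without chlorella-1 replicate 1 at 26 d (0.0583). Vascular markers rose in 3 of 6 cases (median 0.97, adjusted p = 0.0672), the phloem factor APL from 6.94 to 38.7 CPM (2.48 ± 0.16). Floral organ markers had 0 of 3 called (median -0.11, mean -0.19, and a test in the opposite direction with adjusted p = 0.98), PI standing at 1.54 ± 0.71 (adjusted p = 0.0775, 0.0106 to 0.199 over the alternatives). Counts adjusted over the list alone were the same. The lists with 2 measured members were not tested: of dividing cell and root markers 0 were called at 26 d, and of epidermis and trichome markers 1 was higher and 1 lower.

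Other genes named by rule at 26 d went from near nothing to clear levels, or the reverse. BGAL11, a beta-galactosidase gene, ACA3, a carbonic anhydrase gene, and GH9A4, a glycosyl hydrolase gene, had 0 counts in Col and 13.3 ± 7.70, 6.21 ± 3.01 and 5.45 ± 3.33 CPM in chlorella-1, at least 887-fold, 407-fold and 362-fold higher (adjusted p = 6.58e-06, 4.84e-05 and 0.000726). VGD1 and VGDH1, pectin methylesterase genes of pollen, rose from 0.0568 to 23.8 ± 14.2 CPM (8.72 ± 1.04, adjusted p = 0.000221) and from 0.0284 to 13.5 ± 8.05 (8.85 ± 1.0, adjusted p = 0.000168). The phosphatase gene HAI3, induced by abscisic acid, rose from 0.0368 to 17.6 ± 13.5 CPM (8.79 ± 1.17, adjusted p = 6.49e-05). MRD1 (AT1G53480, chromosome 1) fell from 6.31 ± 1.14 to 0.0559 ± 0.0223 CPM (-6.81 ± 0.39, adjusted p = 3.49e-07). ARD3, of methionine salvage, fell from 7.56 ± 9.96 to 0.109 ± 0.189 CPM (-6.04 ± 1.33, adjusted p = 0.00209), a call lost with only the 26 d groups fitted and Col replicate 2 left out (0.0612, 0.00121 to 0.0612 over the alternatives). Of the noncoding genes low at 14 d, MIR850 stood at -4.08 ± 0.39 (adjusted p = 6.2e-06). AT2G01422 (adjusted p = 1.31e-06) and AT3G05955 (adjusted p = 0.000251) were 382-fold (counting interval 105 to 3159) and 31.2-fold (10.4 to 154) lower, from 2 and 3 counts in the mutant. The number of genes called at 26 d was 9888 with only the 26 d groups fitted, and 7753, 7356 and 7083 when Col replicates 1, 2 and 3 were also left out.

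In Col itself, leaves of 26 d against 14 d held more RNA of senescence genes and less RNA of photosynthesis genes. SAG12, with 0 counts at 14 d, reached 113 ± 72.6 CPM, at least 7621-fold higher (adjusted p = 4.9e-05). The regulators NAC055, ORE1 and NAP rose by 9.35 ± 0.54, 6.76 ± 0.44 and 4.22 ± 0.28 on the log2 scale and NYE1 by 2.93 ± 0.21 (adjusted p = 2.55e-06, 3.63e-06, 4.02e-06 and 5.03e-06). RBCS1A changed by -2.40 ± 0.26 (adjusted p = 5.22e-05). Of 20398 genes, 8047 passed, 3935 higher and 4112 lower at 26 d. This balance turned to 4628 higher and 3618 lower with psbA left out of counts and library sizes.

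Of the 22 lists, 13 passed for age in Col. Senescence genes rose in 24 of 29 cases (25 adjusted over the list alone, median 3.49, adjusted p = 3.81e-14, and adjusted p = 0.101 with an estimated correlation). Light-harvesting genes fell in 19 of 20 (20 adjusted over the list alone, median -1.58, adjusted p = 7.24e-08, and adjusted p = 0.332 with an estimated correlation), LHCB6 by -1.93 ± 0.27 and LHCB1.4 by -3.03 ± 0.61. Nuclear photosystem genes fell in 25 of 27 (26 adjusted over the list alone, median -1.31, adjusted p = 2.2e-08, and adjusted p = 0.39 with an estimated correlation). Calvin cycle genes fell in 14 of 17 (15 adjusted over the list alone, median -1.60, adjusted p = 1.6e-06, and adjusted p = 0.339 with an estimated correlation). Chlorophyll biosynthesis genes fell in 16 of 17 (median -1.58, adjusted p = 9.87e-09, and adjusted p = 0.328 with an estimated correlation), GUN5, a magnesium chelatase subunit, from 1544 to 297 CPM (-2.38 ± 0.25). Plastid-encoded ribosomal genes fell in 20 of 21 (median -1.28, adjusted p = 1.54e-10, and adjusted p = 0.328 with an estimated correlation), rpl22 at -1.84 ± 0.20. All 6 ATP synthase genes fell (median -1.27, adjusted p = 0.000226), atpA from 4529 to 1885 CPM, and so did all 11 NDH genes (median -0.86, adjusted p = 0.000113), each list with adjusted p = 0.332 with an estimated correlation. The RNA polymerase list fell in 7 of 8 (median -1.46, adjusted p = 0.000744, and adjusted p = 0.339 with an estimated correlation). Plastid photosystem, cytochrome and Rubisco genes fell in 14 of 27 and rose in 1 (15 lower adjusted over the list alone, median -0.54, adjusted p = 0.00202, and adjusted p = 0.421 with an estimated correlation), with rbcL at -1.30 ± 0.25 and psbA at 0.45 ± 0.30 (adjusted p = 0.256, 0.0349 to 0.45 over the alternatives).

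The plastid transcription machinery fell with age in Col in 7 of 20 cases and rose in 2 (8 lower adjusted over the list alone, median -0.48, adjusted p = 0.00947, and adjusted p = 0.505 with an estimated correlation). Salicylic acid and defence genes rose in 11 of 19 cases and fell in 1 (median 1.48, adjusted p = 0.00155, and adjusted p = 0.5 with an estimated correlation), the marker PR1 from 20.9 to 202 CPM (3.27 ± 0.73, adjusted p = 0.00433). Abscisic acid genes rose in 5 of 11 cases (6 adjusted over the list alone, median 1.25, adjusted p = 0.0222, and adjusted p = 0.496 with an estimated correlation), HB7 from 1.91 to 29.6 CPM, a list call lost without Col replicate 3 at 26 d (0.0553). Chloroplast regulators did not pass (2 of 6 higher, median -0.10, mean 0.36, adjusted p = 0.718), HY5 standing at 1.49 ± 0.32 (adjusted p = 0.00378), GLK1 at -0.13 ± 0.37 (adjusted p = 0.814) and GLK2 at -0.24 ± 0.44 (adjusted p = 0.699). Jasmonate (6 of 13 higher, adjusted p = 0.0626), heat shock (3 of 6 higher, adjusted p = 0.134) and oxidative stress genes (7 higher and 2 lower of 13, adjusted p = 0.134) did not pass as lists, CSD2 being among the lower ones at -3.17 ± 0.26. Flavonoid (3 of 10 higher, 2 adjusted over the list alone, adjusted p = 0.642) and clock genes (2 of 11 higher, 1 adjusted over the list alone, adjusted p = 0.143) did not pass. Neither did markers of floral organs (1 of 3 higher, adjusted p = 0.385), guard cells (1 of 4 lower, adjusted p = 0.329) and vascular tissue (1 of 6 higher and 4 lower, adjusted p = 0.161). Of the lists with 2 measured members, both dividing cell markers and both markers of epidermis and trichomes fell, and 1 root marker rose. Counts adjusted over the list alone were otherwise those over all genes.

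Other genes named by rule for age in Col included DOX1, DIN2, GLYI4, OSM34 and PGAZAT, each with 0 counts at 14 d and at least 7087-fold, 6907-fold, 2488-fold, 1497-fold and 1473-fold higher at 26 d (adjusted p = 1.59e-05, 4.02e-06, 1.72e-05, 9.63e-05 and 5.86e-05). They encode an oxygenase of fatty acids, a dark-induced beta-glucosidase, a glyoxalase, an osmotin-like protein and a polygalacturonase. Among the genes that fell were CER1, of cuticular wax synthesis, from 12.4 to 0.103 CPM (-6.89 ± 0.69), and the expansin EXPA5 from 12 to 0.348 (-5.13 ± 0.71). The xylem protease XCP1 stood at -4.98 ± 0.81, CAD9 at -4.68 ± 1.07 and XTH32 at -4.60 ± 0.81, and the adjusted p of the 5 genes were 3.43e-05, 0.000504, 0.00066, 0.00508 and 0.00112. The myrosinase TGG2 fell from 221 to 4.63 CPM (-5.58 ± 1.41, adjusted p = 0.00869), and DESeq2 gave it no adjusted p.

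In chlorella-1, too, senescence genes rose between 14 d and 26 d and photosynthesis genes fell. NYE1 rose by 7.26 ± 0.25 on the log2 scale, ORE1 by 7.41 ± 0.43 and NAP by 5.19 ± 0.29 (adjusted p = 8.55e-09, 7.27e-08 and 6.31e-08). RBCS1A fell with -4.58 ± 0.28, LHCB1.4 with -7.51 ± 0.76 and rbcL with -4.06 ± 0.28 (adjusted p = 1.13e-07, 3.97e-06 and 2.35e-07), and psbA stood at 0.03 ± 0.30 (adjusted p = 0.936). SAG12, DIN2, DOX1, PGAZAT, the mannanase gene MAN1 and the trypsin inhibitor KTI1 had 0 counts at 14 d and reached 3217 ± 1283, 1590 ± 318, 1258 ± 677, 602 ± 69.5, 566 ± 197 and 380 ± 167 CPM. At 26 d, the cell wall gene XTH31, MSRB6 and the growth genes SAUR24, PRE1 and EXPA5 had 0 counts and were at least 959-fold, 649-fold, 441-fold, 386-fold and 306-fold lower. The plastid gene rps16 was at least 626-fold lower, without a call in limma voom (adjusted p = 0.0841, 4.29e-08 to 0.0841 over the alternatives), and DESeq2 gave MSRB6 no adjusted p. In all, 14520 genes passed, 7183 higher and 7337 lower, or 7625 and 6928 with DESeq2 size factors and 7594 and 6807 with psbA left out.

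Again 13 of 22 lists passed for age in chlorella-1. Every measured member of 6 lists fell. These were the light-harvesting list (20, median -4.67, adjusted p = 2.1e-09, and adjusted p = 0.328 with an estimated correlation), the nuclear photosystem list (27, median -3.74, adjusted p = 2.58e-11, and adjusted p = 0.339 with an estimated correlation) and the Calvin cycle list (17, median -3.94, adjusted p = 6.67e-08, and adjusted p = 0.332 with an estimated correlation). In the plastid they were the ATP synthase (6, median -3.61, adjusted p = 6.98e-05, and adjusted p = 0.332 with an estimated correlation), NDH (11, median -3.50, adjusted p = 4.13e-07, and adjusted p = 0.328 with an estimated correlation) and ribosomal lists (21, median -2.55, adjusted p = 2.1e-09, and adjusted p = 0.328 with an estimated correlation). Plastid photosystem genes fell in 25 of 27 cases (median -1.96, adjusted p = 2.81e-09, and adjusted p = 0.328 with an estimated correlation). RNA polymerase genes fell in 7 of 8 (median -2.74, adjusted p = 0.00106, and adjusted p = 0.339 with an estimated correlation) and chlorophyll genes in 16 of 17 (median -3.45, adjusted p = 3.47e-07, and adjusted p = 0.328 with an estimated correlation). The plastid transcription machinery fell in 18 of 20 and rose in 1 (median -1.59, adjusted p = 0.00018, and adjusted p = 0.375 with an estimated correlation). Senescence genes rose in 24 of 29 and fell in 2 (median 5.19, adjusted p = 6.72e-08, and adjusted p = 0.328 with an estimated correlation), and abscisic acid genes rose in 8 of 11 (median 3.83, adjusted p = 0.0151, and adjusted p = 0.452 with an estimated correlation).

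Heat shock genes rose in 5 of 6 cases with age in chlorella-1 (median 4.99, adjusted p = 0.0492, and adjusted p = 0.505 with an estimated correlation). That call was lost with scaling on nuclear genes (0.0505) and without Col replicates 1 at 14 d (0.0522) and 3 at 26 d (0.0532), chlorella-1 replicates 1 (0.0548), 2 (0.0537) and 3 (0.0543) at 14 d, and chlorella-1 replicates 2 (0.0653) and 3 (0.107) at 26 d. GLK1 at -2.15 ± 0.39 and GLK2 at -2.08 ± 0.46 (adjusted p = 0.000403 and 0.00163) were among the 4 of 6 chloroplast regulators that fell, and 2 rose (adjusted p = 0.642). Salicylic acid genes rose in 7 of 19 cases and fell in 3 (adjusted p = 0.642), and oxidative stress genes rose in 9 of 13 and fell in 3 (adjusted p = 0.0643). Flavonoid genes rose in 6 of 10 (adjusted p = 0.303) and clock genes rose in 6 of 11 and fell in 2 (adjusted p = 0.519). Jasmonate genes rose in 4 of 13 and fell in 5, with a median of -0.68, a mean of 0.53 and a test for higher values (adjusted p = 0.945). Floral markers rose in 1 of 3 cases (adjusted p = 0.544), guard cell markers rose in 3 of 4 and fell in 1 (adjusted p = 0.159), and vascular markers rose in 3 of 6 and fell in 3, with a median of 0.15, a mean of -0.39 and adjusted p = 0.639. Both dividing cell markers fell, 1 root marker rose and 1 fell, and 1 of the epidermis and trichome markers fell.

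The difference between the genotypes in the age change, which is also that of the mutant's effect at 26 d and at 14 d, was tested for each gene, and 8606 of 20398 passed, 4323 positive and 4283 negative. RBCS1A fell with age more steeply in chlorella-1 (difference -2.18, adjusted p = 0.000629), as did LHCB1.4 (-4.48, adjusted p = 0.00164) and rbcL (-2.76, adjusted p = 0.000167), and NYE1 rose more steeply (4.33, adjusted p = 5.78e-06). For ORE1 the difference was 0.65 (adjusted p = 0.347) and for psbA -0.42 (adjusted p = 0.447). GLK1 (-2.02, adjusted p = 0.0107) and GLK2 (-1.84, adjusted p = 0.0354) differed, as did SEN1 (-4.83, adjusted p = 0.000535) and STP1 (-3.23, adjusted p = 0.000165).

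Of the 22 lists, 12 passed this test of the difference. They were the plastid photosystem (24 of 27 members negative, median -1.50, adjusted p = 5.74e-11), ATP synthase (6 of 6, -2.32, adjusted p = 2.24e-05), NDH (11 of 11, -2.75, adjusted p = 5.32e-08) and light-harvesting lists (18 of 20, -3.20, adjusted p = 2.87e-09), each with adjusted p = 0.328 with an estimated correlation. The plastid ribosomal (19 of 21, -1.36, adjusted p = 6.64e-07), nuclear photosystem (27 of 27, -2.55, adjusted p = 3.92e-11) and Calvin cycle lists (16 of 17, -2.18, adjusted p = 1.1e-06) followed, each with adjusted p = 0.339 with an estimated correlation. Chlorophyll genes (12 of 17, -1.17, adjusted p = 0.000129) and the plastid transcription machinery (14 of 20 negative and 1 positive, -1.01, adjusted p = 0.00021) each had adjusted p = 0.375 with an estimated correlation. RNA polymerase genes (5 of 8, -1.15, adjusted p = 0.0341, and adjusted p = 0.5 with an estimated correlation) lost the call without chlorella-1 replicate 3 at 26 d (0.0507). Senescence genes (13 of 29 positive and 3 negative, 1.25, adjusted p = 0.018, and adjusted p = 0.356 with an estimated correlation) had a median of 1.11 without members near 0 counts, and guard cell markers (3 of 4, 1.81) had adjusted p = 0.019 and adjusted p = 0.328 with an estimated correlation.

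**Figure D3:**
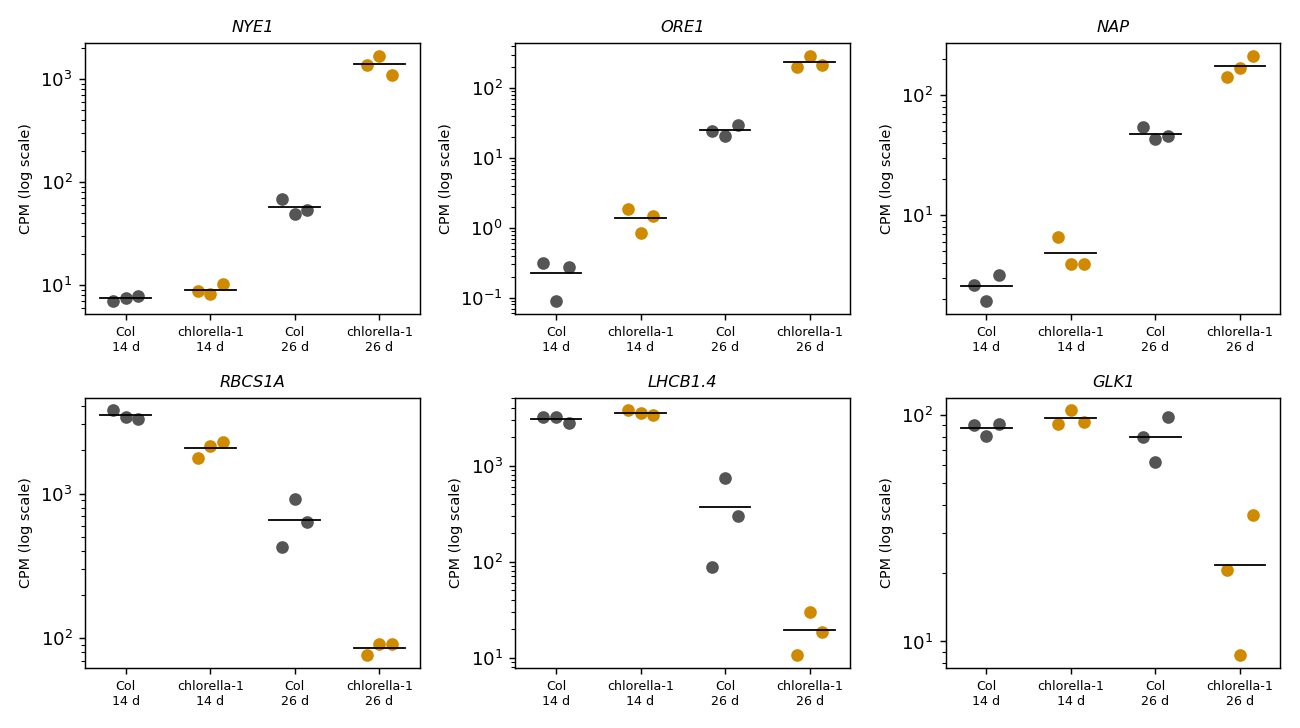
Normalised read counts (CPM, log scale) of NYE1, ORE1, NAP, RBCS1A, LHCB1.4 and GLK1 in each of the 12 libraries, with points for libraries and bars for group means (n = 3). NYE1 averages 57.1 CPM in Col and 1396 CPM in chlorella-1 at 26 d.

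Across genes, which are not independent replicates, the mutant's effects at 14 d and at 26 d were weakly related (Pearson's r = 0.0931, Spearman's rho = 0.168, 20398 genes). Of the 24 genes higher at 14 d, 17 were higher at 26 d, where independent lists would share 7.56, and all 9 lower genes were lower at 26 d (2.86 by independence). Another 2 genes were called in opposite directions at the 2 ages. Both ages share an estimate of the spread, which these expected numbers leave out. Of the 9 lower genes, 6 were near 0 counts in chlorella-1 at 14 d, and 3 of the shared higher genes were near 0 in Col. For such genes, differences between the lines besides the mutation cannot be told apart from its effects. Without chlorella-1 replicate 3 at 14 d, 1 of 4 higher genes was shared (1.23 by independence). Without Col replicate 2 at 14 d, 1 gene was higher. With only the groups compared fitted, a relation chosen after seeing the data, 437 of 1170 higher genes were shared (294 by independence). Of 1415 lower genes in that fit 773 were shared (349 by independence), and 356 genes were called in opposite directions. In the fit of all groups, r was 0.0244 without chlorella-1 replicate 1 at 14 d and 0.0605 without Col replicate 2 at 26 d. The mutant's effect at 14 d and the age change in Col were related at r = 0.395 (rho = 0.489, 19289 genes, fitted without the 26 d mutant group). The Col libraries of 14 d that both share gave r = 0.498 (0.475 to 0.524) in simulations of groups with no change at all. That r is therefore no reference for the observed 0.395. The covariance was 0.401 against 0.0808 simulated, a difference of 0.321. Part of the excess may come from the shared libraries, and without chlorella-1 replicate 1 at 14 d r was 0.227. The mutant's effect at 26 d was related to the age change in Col at r = 0.275 (rho = 0.371), a relation added after seeing the data. Its covariance was 1.07 against -0.0878 simulated, a difference of 1.16. The simulated r of -0.498 again comes from groups with no change and is no reference for the observed r. Without Col replicate 2 at 26 d the observed r was 0.128.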

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

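The tests of explanations in this part were chosen after the results were seen, apart from the counts over other splits of the libraries. Of those counts, the reading for the difference between the ages was changed after its value was seen. What brought most of these results here is that the mutant's effect differed between 26 d and 14 d by a test of the difference itself. It did so for 8606 genes by edgeR with adjusted p under 0.05. For 2 of 100 drawn splits of the libraries, the real one included, that count was as large, with 8732 in the highest of the other splits. The 6 drawn splits that kept the 26 d groups whole and mixed only the 14 d libraries gave 8069 to 8732, and the 93 that mixed 26 d libraries gave 0. The splits thus follow the structure of the 26 d groups and do not show whether chance can be excluded for a difference between the ages. For the other comparisons the splits are too few for a share under 0.05: 1 of 10 splits, the real one, gave as many genes for chlorella-1 against Col at 14 d (33, highest other 0), 1 of 10 at 26 d (12921, highest other 4), 1 of 10 for age in Col (8047, highest other 0) and 1 of 10 for age in chlorella-1 (14520, highest other 0).

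Among gene lists, the medians of that difference were -1.50 for plastid photosystem, -2.32 for ATP synthase, -2.75 for NDH, -1.15 for RNA polymerase and -1.36 for plastid ribosomal genes. They were -3.20 for light-harvesting, -2.55 for nuclear photosystem, -2.18 for Calvin cycle, -1.17 for chlorophyll and -1.01 for plastid transcription genes, 1.25 for senescence genes and 1.81 for guard cell markers. All of these lists passed camera with the preset correlation and none with an estimated one, and the RNA polymerase list did not pass without chlorella-1 replicate 3 at 26 d (adjusted p = 0.0507). With fry, 14 lists passed for the difference, these 12 among them.

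Single genes named in the report that passed that test of the difference, on the log2 scale, were as follows. Photosynthesis and plastid genes had negative differences: LHCB1.4 -4.48, CHLM -3.42, LHCB6 -3.20, PSAG -3.19, ndhA -2.97, rbcL -2.76, SIG4 -2.72, atpH -2.55, atpA -2.38, GUN5 -2.31, rpoC1 -2.24, RBCS1A -2.18, GLK1 -2.02, psbE -1.87, GLK2 -1.84, rps2 -1.8, CHLI1 -1.17 and rpl22 -0.85, while RPOTmp had 1.74 and SAPX 0.84. Senescence genes had NYE1 4.33, NYC1 3.64, NAC055 2.45, PPH 2.16 and NAP 0.97, against SEN1 -4.83, ORS1 -1.93 and SAG101 -1.6. Hormone, stress and clock genes had JAZ1 4.06, HSP70 3.42, HY5 3.21, AOX1A 2.82, NCED3 2.58, HB7 2.19, LUX 1.72, WRKY33 1.57 and TT5 1.0, against PDF1.2 -8.02, WRKY70 -2.08, OPR3 -1.56, CAT2 -1.26 and RVE8 -1.2. Of the rest, HAI3 had 9.55, CER1 5.39, MIR850 3.67, KAT1 2.87 and APL 2.63, and DYL1 -3.09, STP1 -3.23 and PP2-A13 -1.92. For genes near 0 counts in a group the adjusted p of the difference is given in place of its size: BGAL11 0.000979, XTH31 0.00168, PRE1 0.00274, MIR5026 0.00458, PDF1.2c 0.00504, PDF1.3 0.0051, MIR863 0.00521, SAUR24 0.0092, MSRB6 0.00967, PDF1.2b 0.009997, ACA3 0.0138, KTI1 0.0139, rps16 0.0201 and AT1G75945 0.0374.

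The share of counts from plastid-encoded genes lay above Col in every chlorella-1 library at 14 d (3.79 percentage points on average) and below it in every one at 26 d (-16.1), a difference between the ages that was not tested. Rows that name no gene, all mitochondrial and outside the gene tests, held 0.17% of counts in chlorella-1 at 26 d, against 0.0971% in Col at 26 d.

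Photosynthesis transcripts were lower in chlorella-1 at 26 d. A single library as the cause is argued against by the median log2 fold change of nuclear photosynthesis genes, which was at most -2.64 with any 1 library left out, in the fits of all groups and of only the 26 d groups. With psbA left out of counts and library sizes the same median was -2.89, but TMM scaling gives 1 gene little weight, so this refit decides little. A larger share of psbA in the mutant is argued against by the shares at 26 d, which averaged 52.1% in chlorella-1 and 57.4% in Col. Dilution of leaf RNA by RNA of other cells stays open: 38.1% of the 5063 nuclear genes of at least 10 CPM in Col leaves were called higher. However, scaling centres the calls and other cells express many of these genes. A limit of 10% set for this test was therefore dropped after the value was seen. Guard cell markers (3 of 4) rose, and so did pollen genes (19 of 20), most of which could pass the filter only through chlorella-1 at 26 d. An effect of the genotype, and a difference between the plants in developmental stage or in growth conditions, stay open and were not tested.

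Pollen genes were higher in chlorella-1 at 26 d: 19 of 20 measured genes of a list of 26, written after VGD1 and VGDH1 had been noticed and without them, rose (median log2 fold change 7.66, or 6.74 with genes near 0 counts at their bound, adjusted p = 2.34e-06, and adjusted p = 0.291 with an estimated correlation). Their summed level was 107 CPM against 19.6 in Col, most of the latter from TUA1, which leaves express as well, and the most abundant were TUA1 (25.8 CPM), AT3G07820 (19.1) and LAT52-like (11.3). Most of the 20 lay near 0 in the other groups, so they could pass the filter only through chlorella-1 at 26 d. Listed genes low in every group were not measured. The 19 of 20 and the adjusted p of the list thus follow in large part from the filter. RNA of pollen from a single source would keep its genes in 1 ratio between libraries: the log2 ratio of replicate 2 to the mean of the other two had a median of -1.77 and an SD of 0.883 over 18 genes (0.861 in the median random list, 53.7% of 10000 at or below) and of 0.817 without TUA1 (39.7% at or below), much of it from ACT12 and PRF4, but the limit for excluding that source was moved from 50% to 95% of random lists after the value was seen, and under the first limit the test would have argued against it, so it is left open. RNA of whole flowers is left open as well, since the petal and stamen regulator PI stood at adjusted p = 0.0776 (0.0106 to 0.199 over the alternatives). A change of these genes in the mutant's leaf cells was not tested and cannot be told apart from either.

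A rule written after the values were seen found 9 genes near 0 in 1 genotype and present in the other at 14 d, and called in the same direction at 26 d. In chlorella-1, MRD1, AT2G01422, AT3G05955, MIR850, MIR863 and MIR5026 were near 0, MRD1 at 14 d being 270-fold lower from 3 counts (counting interval 92.2 to 1313), MIR5026 89.2-fold lower from 2 counts (24.4 to 741) and MIR863 at least 29.7-fold lower. In Col, AT1G75945 and AT3G05170 (0 counts at 14 d, at least 53.4-fold and 75.9-fold higher in chlorella-1) and AT3G55920 (0 counts at 26 d, at least 80.1-fold higher) were near 0. At 14 d, in the fit of all groups, MIR863, AT3G05955, AT1G75945, AT3G05170 and AT3G55920 lost the call without Col replicate 2 (adjusted p = 0.0694, 0.132, 0.137, 0.199 and 0.135). Some of these were also lost without Col replicates 1 (up to 0.21 for AT3G05170) and 3 (0.144 for AT3G05170) and chlorella-1 replicates 1 (0.177 for AT3G05170), 2 (0.128 for AT3G05170) and 3 (0.108 for AT3G05170) at 14 d, and without Col replicate 3 (0.0524 for AT1G75945) and chlorella-1 replicates 1 (0.0782 for AT3G05170) and 3 (0.0562 for AT3G05170) at 26 d. The ranges over the alternatives at 14 d ran from 7.58e-06 to 0.0793 for MIR863, 1.76e-08 to 0.132 for AT3G05955, 2.94e-07 to 0.137 for AT1G75945, 3.31e-07 to 0.21 for AT3G05170 and 4.06e-15 to 0.135 for AT3G55920. With only the 14 d groups fitted, all 9 genes kept the call at 14 d without any 1 library of those groups.

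Of explanations for these 9 genes, a single lesion acting on neighbours is argued against for the 9 together by their lying on 4 chromosomes. For MIR5026, MIR850 and MIR863, which all overlap AT4G13495, that does not test a local lesion. Loss of the whole host RNA of the 3 microRNA genes is argued against by AT4G13495, which stood at a log2 fold change of 0.045 (SE 0.237) at 14 d, although it fell at 26 d (-1.0, adjusted p = 0.00358) and how reads of overlapping genes were assigned is not stated. Differences between the lines besides the mutated gene, a candidate explanation for genes such as these 9, cannot be told apart from effects of the mutation, because the mutated gene is not named in the table and no further line was sequenced. Neither was tested further.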

How the results depend on the processing

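Fits without the 26 d mutant group, with psbA left out, and of only the groups compared with a block or with libraries left out were chosen after seeing the data, as were the relation of the 26 d effect to age and its alternatives and the relations fitted on only the groups compared. The count at 14 d (33) was the least stable: 381 in DESeq2, 2713 with only the 14 d groups fitted, 534 without the 26 d mutant group, 11 with the replicate number as a block and 2300 with only the 14 d groups and that block. In the fit of all groups it was 6, 5 and 9 without Col replicates 1, 2 and 3 at 14 d, 6, 16 and 9 without chlorella-1 replicates 1, 2 and 3 at 14 d, and 17 and 232 without chlorella-1 replicates 1 and 2 at 26 d. With only the 14 d groups fitted it was 1518, 1804 and 2046 without Col replicates 1, 2 and 3 and 1547, 1877 and 2349 without chlorella-1 replicates 1, 2 and 3. Fitting fewer groups changes the estimate of the spread, since the 26 d mutant libraries vary most; beyond this the cause was not tested. Of the 33 genes, all were called in DESeq2, with only the 14 d groups and without the 26 d mutant group. They all kept the call as well with only the 14 d groups fitted and any 1 library of those groups left out. With single libraries left out, the counts were 11880 to 13152 for chlorella-1 against Col at 26 d (with only the 26 d groups fitted 7753, 7356 and 7083 without Col replicates 1, 2 and 3, and up to 10420), 5967 to 10427 for age in Col, 13665 to 14804 for age in chlorella-1 and 6930 to 9516 for the difference of the age changes. With an absolute log2 fold change of at least 1, 5258 of the 8047 genes changed with age in Col remained, by construction of that limit.

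Camera with an estimated correlation called 0 lists in each of the 5 comparisons, where the preset correlation called 9, 14, 13, 13 and 12. In contrast, fry called 2 lists at 14 d (chlorophyll, adjusted p = 0.0459, and senescence genes, 0.00504), 16 in each of the other 3 simple comparisons and 14 for the difference. At an unadjusted p under 0.05 the genes called by edgeR at 14 d numbered 1851. With single libraries left out camera called 7 to 12 lists at 14 d, 13 to 15 at 26 d, 13 to 14 for age in Col, 12 to 13 for age in chlorella-1 and 12 to 13 for the difference.

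The plastid share turned with psbA left out, to -0.729 percentage points for chlorella-1 against Col at 14 d and to -11.7 for age in Col. In both, psbA itself held the larger share: 48.0% in chlorella-1 at 14 d and 57.4% in Col at 26 d, against 40.3% in Col at 14 d. No such turn came for chlorella-1 against Col at 26 d (-26.2) or for age in chlorella-1 (-37.1). With single libraries left out the differences of shares ran from 2.81 to 4.43 at 14 d, -18.3 to -12.8 at 26 d, 3.39 to 5.01 for age in Col and -17.7 to -12.2 for age in chlorella-1. The correlation of the effects at 14 d and 26 d was 0.179, and that of the 14 d effect and age in Col 0.501, with only the groups compared fitted, where the cause was not tested. With single libraries left out the correlations ran from 0.0244 to 0.105, 0.227 to 0.441 and, for the 26 d effect and age, 0.128 to 0.277. The first dropped from 0.0931 to 0.0244 without chlorella-1 replicate 1 at 14 d and to 0.0605 without Col replicate 2 at 26 d, the second from 0.395 to 0.227 without chlorella-1 replicate 1 at 14 d, and the third from 0.275 to 0.128 without Col replicate 2 at 26 d.

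Deviations of same-numbered libraries correlated weakly (-0.114 to 0.141), which gives no sign of pairing but cannot exclude it with 3 libraries per group. With the replicate number as a block the genes called were 11, 12647, 7472, 14324 and 8117, the lists 9, 14, 13, 13 and 12 as before, and the differences of shares were the same, with an exact permutation p of 0.25, the smallest that 3 pairs allow. The correlations with the block were 0.0924 and 0.394.

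Scaling moved the median log2 fold change of all genes by over 0.1 in some fits. With DESeq2 size factors it went from -0.114 to 0.0186 at 26 d, from -0.106 to 0.0178 for age in chlorella-1 and from -0.112 to 0.0246 for the difference, and with psbA left out from 0.0102 to 0.11 for age in Col and from -0.106 to 0.0052 for age in chlorella-1. No named gene reversed under any alternative. Of the named genes called, 5 of 18 at 14 d, 53 of 58 at 26 d, 26 of 27 for age in Col and 18 of 20 for age in chlorella-1 passed under every alternative run. Depth limits the genes near 0 counts in a group.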

Other observations

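The gene groups in this part were tested after the values of several groups had been looked at, so their adjusted p, over 25 tests, understate the choice. For the relation to the age change in Col, the limit was changed after its values were seen and before the further test given last. Outside the fixed lists, chlorella-1 leaves at 26 d held less RNA of nuclear ribosomal protein genes and more of autophagy genes. Both groups were picked by description, which did not separate ribosomal proteins of the cytosol from those of plastids or mitochondria. Of 317 nuclear genes described as ribosomal proteins, 243 fell and 11 rose against Col (median log2 fold change -1.0, adjusted p = 2.75e-16, and adjusted p = 0.111 with an estimated correlation). Of 17 autophagy genes, 14 rose and 1 fell (median 1.79, adjusted p = 5.86e-06, and adjusted p = 0.111 with an estimated correlation). At 14 d the ribosomal protein genes already lay lower as a group, with 0 called by edgeR singly (median -0.39, adjusted p = 8.37e-34, and adjusted p = 0.0773 with an estimated correlation).

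Protein-coding genes of the mitochondrial genome moved opposite to those of the plastid at 26 d: 24 of 31 rose and 1 fell (median 0.83, adjusted p = 1.72e-06, and adjusted p = 0.291 with an estimated correlation). Their share of counts was 1.08% ± 0.259 in chlorella-1 and 0.504% ± 0.0661 in Col (SD, n = 3, exact permutation p = 0.1, the smallest possible). Small nuclear RNA genes, which are near-identical copies and which total RNA libraries capture, rose in 26 of 28 cases (median 2.35, adjusted p = 5.37e-05, and adjusted p = 0.458 with an estimated correlation), with a share of 0.559% ± 0.184 against 0.154% ± 0.0781 (SD, n = 3, exact permutation p = 0.1). Transfer RNA genes were looked at as well and not tested.

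A hypothesis is that leaves of chlorella-1 at 14 d lie further along the change that Col leaves undergo between 14 d and 26 d. The covariance of the mutant's effect at 14 d with the age change in Col exceeded the simulated value of unchanged groups with shared Col libraries by 0.321. The simulated correlation of 0.498 (0.475 to 0.524) comes from groups without an age change, so the observed 0.395 cannot be set against it. This comparison leaves the shift open, although the covariance alone had first been read as support. A further test, with its limits set after these values but before its own, used 1 Col library of 14 d for the mutant's effect and the other 2 for the age change. It took differences of log2 CPM and not edgeR's fold changes, so its covariances cannot be set against the 0.321. The covariance of single chlorella-1 libraries was 0.14 to 0.421 in 9 arrangements (r of 0.178 to 0.45), the highest with chlorella-1 replicate 1, and that of single Col libraries against each other was -0.0882 to 0.0882 in 6 arrangements. The latter took each pair of Col libraries in both orders, so their range is symmetric by construction. Their age change rested on the 1 remaining Col library of 14 d. All arrangements reuse the same libraries and are not independent. The values go with a shift along the age change of Col, for which 3 Col libraries are a small reference. Among senescence genes at 14 d, ORS1 was higher (adjusted p = 0.00295, 4.99e-16 to 0.0322 over the alternatives), while NYE1 did not pass (0.769, 0.085 to 1.0). Whether the mutant ages sooner, or its leaves were of another stage or size when collected, could not be told from these libraries.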
